A study of Mus musculus with 6 samples.

How the data were processed

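Polyadenylated RNA of 6 BaF3 libraries was measured: 2 each from cells with the Clover plasmid (con), the Clover plasmid with the Notch1 intracellular part (ICN) and its mutated form (CTdel). The libraries were made with the MGIEasy mRNA kit, per the labels' protocols. The submitters' processing notes name HISAT2, Bowtie2 and RSEM and the builds hg19 and mm10, with no version or role for each. The authors deposited FPKM per gene, that is fragments scaled by transcript length and library size, in a table for each replicate number, per the file headers. The tables gave NCBI Gene IDs, symbols and annotation terms for 17877 and 17868 genes, of which 16799 were in both. In the deposited tables, 26 symbols had turned into dates and were restored from their Gene IDs, and 18898 of the 18946 IDs were found in the RefSeq gene table for GRCm38.p6, the assembly behind mm10, from which coordinates were taken. The table of replicate 1 held 341 genes at 0 in its 3 libraries and that of replicate 2 held 0 such genes, so the tables were not filtered alike.

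FPKM keep no read totals. Depth was compared through microRNA and small nucleolar RNA genes of up to 100 bases. Genes of equal length share the FPKM of a single read within a library, so the lowest value above 0 was read per library at each of 21 lengths with at least 4 genes, with no bound on the ratio between libraries. The relative depth is the median over lengths of the value in con replicate 1 over that in the library. In each library at least 11 of the 21 lengths lay within 2% of that median, and at the others the lowest value was often a multiple of the step or a shared read. No interval or detection limit was computed, since read counts are unknown.

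Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the spread, 2-sided, and Benjamini-Hochberg adjustment over 11050 genes, those in both tables with FPKM of at least 1 in at least 2 libraries. The model held the 3 groups and the table as a term, fitted to all 6 libraries, which left 2 residual degrees of freedom beside a median prior of 3.82. The threshold was an adjusted p under 0.05. Fixed gene lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over 22 lists, and again with the correlation estimated from the residuals and with fry. With the estimated correlation 0 of the 11, 7, 7 and 8 list calls held (ICN, CTdel, CTdel against ICN, both forms). That test also rests on the 2 residual degrees of freedom, so a lost call there cannot be put down to correlation between genes alone. T-lineage genes in ICN had an estimated correlation of −0.185, under the preset 0.01, yet camera's p went from 0.00197 to 0.0874. The other lists called in ICN had estimates above the preset, from 0.0581 (erythroid and megakaryocyte markers) to 0.925 (ribosome biogenesis), with 0.854 for the interferon response. At the preset, camera's p may therefore be far too small for those lists, and their members do not count as independent genes. Fry, which asks whether a list's genes move one way, gave adjusted p of at least 0.133. Its mixed test, which lets genes move both ways, gave adjusted p under 0.05 for some lists. A list of fibroblast and endothelial markers had 2 tested genes and was not tested. Enrichment of the deposited Biological Process terms used the hypergeometric test over tested genes with a term, for terms with 10 to 1000 of them.

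The lists, the tests and the alternatives were set before the data were examined, except where the closing section says otherwise. The genes named were Notch1; per pairwise comparison the 10 with the largest rise and the 10 with the largest fall among called genes with the same sign in both replicates and a mean FPKM of at least 1 (where fewer passed, also those with the smallest p up to 5 in all); tested canonical Notch targets; and up to 4 members with the smallest p of lists that passed, or up to 2 of others. Gzmb in ICN, and the genes named for both forms together, are outside that rule and were chosen after their values were seen. Alternatives covered the table term, the pseudocount, the filter, the scaling, the spread, the libraries fitted, genes of 1 table, the threshold and each library left out. Where a library left out leaves a group with 1 library, that library is assumed to vary like the other groups. Such a lone library is matched by its own group term and adds nothing to the spread. Leaving out either library of a group thus gives nearly the same spread. For the other 2 groups it amounts to fitting them alone, so these settings are not separate results.

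On simulated data with 200 of 11050 genes changed, the fit called 73.6% of those changed by 2 on the log2 scale and 96.4% of those changed by 3 for ICN against con, 76.8% and 94.8% for CTdel against con, and 76.8% and 96% for CTdel against ICN. Of changes of 1 it called 3.6%, 4.8% and 4%. In the real data the transfected gene Notch1 did not pass in ICN or in CTdel. In ICN 0 of 24 interferon-response genes passed, at a median change of 2.64, with medians of 1.19 and 4.46 in replicates 1 and 2. The simulated shares therefore need not hold for genes whose replicates differ that much, and a gene that was not called is not shown to be unchanged. Unchanged groups were simulated 50 times for the shared con libraries. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, with scipy 1.17.1, and drawn with matplotlib 3.10.9.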

Results

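RNA was sequenced from BaF3 cells, a mouse pro-B line that needs interleukin-3 for growth, grown in 2 ng/mL interleukin-3 and 10% serum and sorted 24 h after nucleofection with plasmid. The con group received a plasmid for Clover, a green fluorescent protein, alone. The ICN group received Clover with the intracellular part of Notch1, the form that Notch receptors release to act in the nucleus, and the CTdel group received the mutated ICN plasmid. What CTdel stands for, and the species of the ICN sequence, are not given in the sources used here. No group received the ICN plasmid without its ICN sequence. In changes against con, effects of ICN and of added plasmid DNA can therefore not be told apart. Each group had 2 libraries, numbered 1 and 2, and the deposited FPKM values of each number came in a table of their own, so every change was taken within a table. FPKM summed to between 489693 and 507894 per library. Read totals are unknown, but the lowest values above 0 of small RNA genes of equal length put the depth of the libraries at 0.963 to 1.08 times that of con replicate 1. Genes with FPKM above 0 numbered 14966 ± 21.2 in con, 16680 ± 377 in ICN and 15710 ± 158 in CTdel (SD, n = 2). The tests covered 11050 genes. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries only. Changes are on the log2(FPKM + 1) scale, which understates those of low genes.

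The first question was whether the transfected gene and the genes that Notch is known to switch on were higher. Notch1 (Gene ID 18128, chromosome 2, 26457902 to 26503822 in GRCm38) stood at FPKM 0.89 and 1.72 in con replicates 1 and 2, at 190 and 888 in ICN, and at 84.9 and 25.4 in CTdel, so all 4 libraries with an ICN plasmid lay above both con libraries. Reads of the plasmid and of the cell's own gene are not separated in these values. The log2 change was 7.51 in ICN (adjusted p = 0.103) and 4.39 in CTdel (adjusted p = 0.0947), and with both forms set against con together Notch1 rose by 5.95 (adjusted p = 0.0336). Dtx1, a classical Notch target that encodes a regulator of the pathway, rose in CTdel, from 0.025 ± 0.0354 in con to 12.1 ± 4.81 (SD, n = 2; log2 change 3.63, adjusted p = 0.017). In ICN it had a mean of 1.94 ± 1.3 (log2 change 1.45, adjusted p = 0.172).

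The other canonical targets did not pass singly, and the list with Dtx1 in it did not pass camera's test of a common direction. Fry's mixed test, which lets genes move both ways, gave the list adjusted p of 0.0439 in ICN, 0.00321 in CTdel and 0.00679 for both forms together. In CTdel against ICN it was 0.118. That mixed test passed for other lists too, such as B-lineage genes in ICN (0.0477) and CTdel (0.0378). Il2ra, the alpha chain of the interleukin-2 receptor, had FPKM 69.2 ± 57.1 in con, 323 ± 70.8 in ICN and 587 ± 247 in CTdel, with adjusted p of 0.201 and 0.0861 for the forms. Ptcra, the pre-T-cell receptor alpha chain, had 1.42 ± 0.0707 in con, 4.54 ± 0.587 in ICN and 1.25 ± 0.382 in CTdel (log2 change 1.19 in ICN, adjusted p = 0.169). Bcl2, which blocks apoptosis, had 46.6 ± 0.453 in con, 19.7 ± 9.02 in ICN and 13.7 ± 3.32 in CTdel (adjusted p = 0.172 and 0.0557). Myc had 196 ± 2.53, 101 ± 16.3 and 182 ± 13.8. Mean changes of Igf1r and Hes6 against con were at most 0.31 in either direction. For Igf1r in CTdel that mean joins opposite changes, from FPKM 20.3 in con to 16.2 in replicate 1 and from 10.0 to 19.9 in replicate 2. Hes1, Hes5 and Nrarp stayed at or below FPKM 0.37 in all 6 libraries and were not tested. Of the 7 canonical targets tested, 0 passed in ICN and 1 in CTdel over all genes. Adjusted over the list alone, 3 rose and 2 fell in ICN, and 2 rose and 1 fell in CTdel. The list test gave adjusted p = 0.908 for ICN and 0.425 for CTdel, but without CTdel replicate 1 the list lay higher in CTdel than in con (adjusted p = 0.0397) and than in ICN (0.0328).

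**Figure D1:**
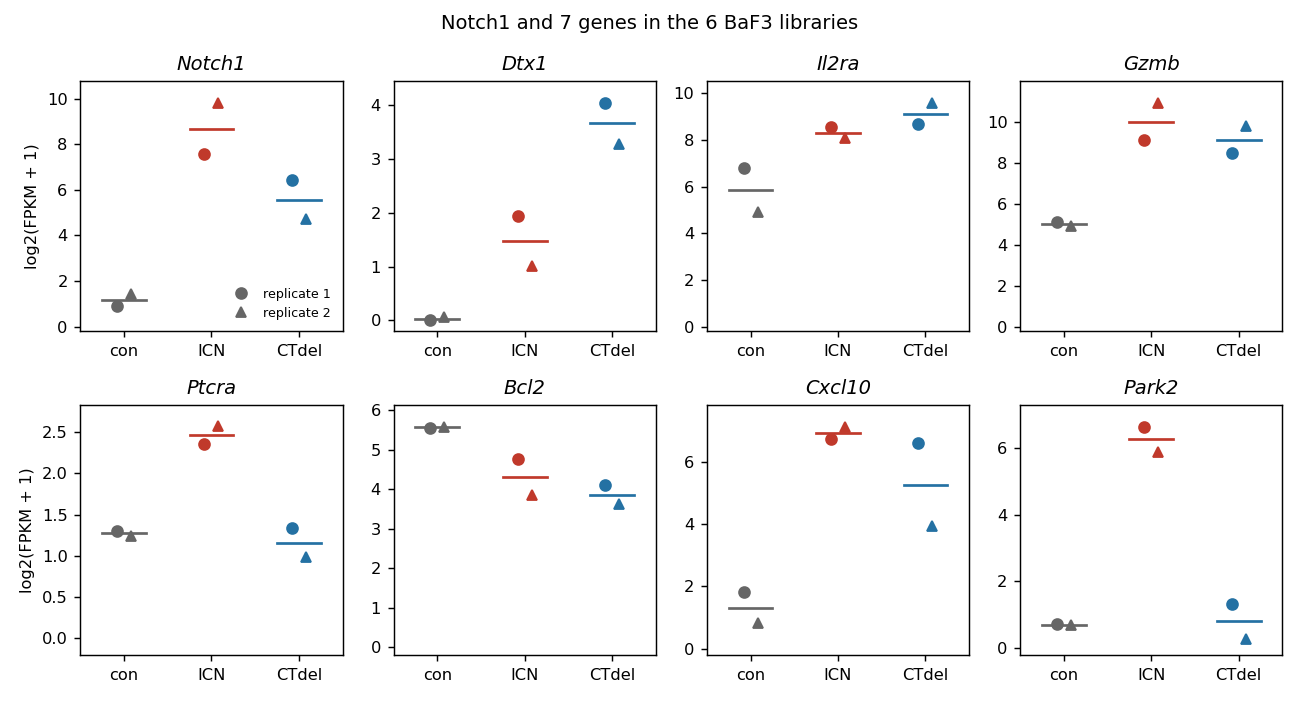
FPKM of Notch1 and 7 genes in each library, as log2(FPKM + 1) on the vertical axis, by group on the horizontal axis. Circles are replicate 1, triangles replicate 2, and lines the means of n = 2. Park2 is high in both ICN libraries and Dtx1 is highest in both CTdel libraries.

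With ICN, 4 genes rose against con and 0 fell. Park2, which encodes the ubiquitin ligase parkin, went from FPKM 0.635 ± 0.0212 to 77.5 ± 28.3 (SD, n = 2; log2 change 5.54), and Pbld1 from 0.38 ± 0.099 to 22 ± 1.46 (log2 change 4.06). Dusp1, a phosphatase that shuts off MAP kinases, rose by 3.33, and Ptafr, the receptor of platelet-activating factor, by 3.15. Each had an adjusted p of 0.013 in limma's test and was higher in both replicates, but with a pseudocount of 0.1 the adjusted p of Park2 and Pbld1 was 0.0502, and with the table left out of the model that of Dusp1 was 0.0821. The next genes did not pass: Slc11a1, a metal transporter of phagosomes, had a log2 change of 2.79 (adjusted p = 0.0737), and Gzmb, the cytotoxic protease granzyme B, had 31.6 ± 3.73 in con and 1230.6 ± 953 in ICN (log2 change 4.99, adjusted p = 0.0737). Lower values that did not pass were those of Dmpk (−1.58), B3gnt7 (−1.65) and the hexokinase Hk3 (−1.49), with adjusted p from 0.103 to 0.12, and of the small nucleolar RNA genes Snora19 and Snord99 (adjusted p = 0.108 and 0.12). Snora19 stood at 2.68 and 2.49 in con and 0 in ICN, and these con values were the lowest above 0 among small RNA genes of 56 bases. It may thus be a single read against none. Snord99 stood at 2.68 and 19.9 in con and 0 and 2.76 in ICN, where 2.68 and 2.76 were such lowest values.

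Interferon-response genes were the group farthest above con in ICN. All 24 had a positive change, with a median of 2.64 (camera adjusted p = 1.95e-16, and adjusted p = 0.775 with an estimated correlation), although 0 of them passed over all genes against 24 adjusted over the list alone. The chemokine Cxcl10 had 1.66 ± 1.27 in con and 122 ± 23.3 in ICN (log2 change 5.61, adjusted p = 0.103). Ifit3, an antiviral protein induced by interferon, had a log2 change of 5.88 (adjusted p = 0.111), and Ifit2 one of 2.69 (adjusted p = 0.103). The median was 1.19 in replicate 1 and 4.46 in replicate 2. Of the 17 NF-kB targets 16 had a positive change, with a median of 1.45 (adjusted p = 2.78e-08, and adjusted p = 0.775 with an estimated correlation), and 11 rose adjusted over the list alone. Nfkbia, the inhibitor that NF-kB itself induces, had a log2 change of 2.37 (adjusted p = 0.113), and the adhesion molecule Icam1 2.23 (adjusted p = 0.144). All 15 genes of the p53 response had a positive change, with a median of 1.23 (adjusted p = 9.62e-06, and adjusted p = 0.775 with an estimated correlation). Their median was 0.34 in replicate 1 and 2.12 in replicate 2, and 6 rose adjusted over the list alone. The death receptor Fas had 5.67 ± 2.64 in con and 32.7 ± 21.6 in ICN (log2 change 2.23, adjusted p = 0.207), and Trp53inp1 had a log2 change of 2.40 (adjusted p = 0.222).

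Other lists moved less. T-lineage genes (5 tested, median 0.70, adjusted p = 0.00618, and adjusted p = 0.775 with an estimated correlation) and myeloid markers (13 tested, median 0.50, adjusted p = 0.036, and adjusted p = 0.843 with an estimated correlation) lay higher in ICN, with Ptcra at a log2 change of 1.19 and the myeloid regulator Spi1 at 1.74 (adjusted p = 0.169 and 0.12). Erythroid and megakaryocyte markers lay lower (7 tested, median −0.72, adjusted p = 0.019, and adjusted p = 0.775 with an estimated correlation), among them the erythroid factor Klf1 (−1.59, adjusted p = 0.155). Over all genes 0 members of these 3 lists passed, and adjusted over the list alone 2 T-lineage genes and 4 myeloid markers rose and 4 erythroid and megakaryocyte markers fell. Ribosome biogenesis and MYC targets (30 tested, median −0.53, adjusted p = 8.18e-07), cell cycle genes (30 tested, median −0.39, adjusted p = 0.000372), glycolysis and hypoxia genes (21 tested, median −0.38, adjusted p = 0.00023), cholesterol synthesis genes (21 tested, median −0.33, adjusted p = 0.00929) and cytosolic ribosomal proteins (26 tested, median −0.15, adjusted p = 0.0463) also lay lower. With an estimated correlation the adjusted p of these 5 ran from 0.775 to 0.843. Examples are Npm1 (−0.69), the mitotic kinase Plk1 (−0.76), Hk2 (−1.04), Mvk (−0.56) and Rpl3 (−0.40), none of which passed over all genes or over its list alone. The cell cycle median was 0.06 in replicate 1 and −0.90 in replicate 2, and without ICN replicate 2 the cell cycle and cholesterol lists turned upward (adjusted p = 0.680 and 0.313). Without con replicate 2 the adjusted p was 0.626 for cell cycle, 0.893 for cholesterol synthesis, 0.315 for ribosome biogenesis and 0.0843 for erythroid and megakaryocyte markers. Without con replicate 1 it was 0.0678 for glycolysis. Without ICN replicate 1 it was 0.0526 for T-lineage genes and 0.828 for both myeloid markers and ribosomal proteins, lists that also lost their calls without con replicate 1 (0.782 and 0.650) or CTdel replicate 1 (0.0543 and 0.183) or 2 (0.0529 and 0.182), and with the table left out of the model (0.113 and 0.0826). Quantile normalization ended the call of ribosomal proteins (0.934), and fitting without a filter on low genes those of T-lineage genes (0.0682) and erythroid and megakaryocyte markers (0.0680). The remaining 11 lists did not pass, with adjusted p from 0.0613 for oxidative phosphorylation to 0.908 for the canonical Notch targets, and 3 of them passed under another setting: heat shock proteins and oxidative phosphorylation lay lower without con replicate 1 (0.00187 and 0.00238) or ICN replicate 1 (0.0153 and 0.0278), and the amino acid stress list without ICN replicate 2 (0.0467). In these libraries the 43 tested histone cluster genes had a median change of 1.16, and the 11 tested small nuclear and Y RNA genes one of 1.35, with 0 past the threshold. The test had 1663 genes at an unadjusted p under 0.05, and without a filter on low genes 0 passed, with 2328 at an unadjusted p under 0.05. The count moved with every library left out: 1470 genes without ICN replicate 1, 147 without ICN replicate 2, 39 and 11 without con replicates 1 and 2, and 161 and 160 without CTdel replicates 1 and 2.

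With CTdel, 156 genes changed against con, 144 higher and 12 lower, and 98 of the higher genes and 2 of the lower ones by over 4 times. The 10 largest rises among the named genes ran from Hsd11b2 to Cd244. Itgax, the integrin subunit CD11c, went from FPKM 0.01 ± 0.0141 to 27.5 ± 7.07 (SD, n = 2; log2 change 4.80, adjusted p = 0.017), and Gzmb from 31.6 ± 3.73 to 622 ± 382 (log2 change 4.11, adjusted p = 0.0261). Ocstamp, needed for the fusion of osteoclasts, was listed at 0 in both con libraries and stood at 34.2 and 24 in CTdel (adjusted p = 0.017), and Treml4, a receptor of myeloid cells, was listed at 0 in con and stood at 67.9 and 17.3 (adjusted p = 0.0265). Hsd11b2, which inactivates glucocorticoids, rose by 5.53 (adjusted p = 0.0272), complement factor B (Cfb) by 5.44 (adjusted p = 0.0486, with FPKM 200 and 23.8 in CTdel and 0.71 and 0.55 in con), the decoy death receptor Tnfrsf23 by 4.49, Dusp1 by 4.36, Slc26a11 by 4.05 and Cd244, a receptor of natural killer cells, by 3.92. Without con replicate 1 the adjusted p of Hsd11b2 was 0.0581, while those of Cfb and Treml4 were 0.137 and 0.0529 with the table left out of the model. The log2 change of Cfb was 3.80 without con replicate 1 and 7.08 without con replicate 2. Its adjusted p was 0.0934 with quantile normalization.

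Transcription factors, receptors and a mast cell protease were among the genes that fell, while the mast cell and basophil list did not pass. Gata2, a transcription factor of haematopoietic progenitors and mast cells, went from 215.0 ± 32.2 to 68.2 ± 9.18 (SD, n = 2; log2 change −1.64, adjusted p = 0.0261), and its partner Zfpm1 from 167 ± 72.8 to 45.3 ± 14.4 (log2 change −1.82, adjusted p = 0.0379). Cpa3, a mast cell protease, had a log2 change of −1.88 (adjusted p = 0.0437), F2r, the thrombin receptor, −1.91, Mycn −1.70, the cytokine gene Flt3l −1.72, the microRNA gene Mir1949 −1.72, Hk3 −1.62, Muc13 −2.02 and Dmpk −2.04. Mir1949 stood at 15.6 and 24.6 in con and 4.64 and 5.92 in CTdel. The lowest value above 0 at its length, 70 bases, was 1.55 in CTdel replicate 1, so it may rest on few reads. Without a filter on low genes none of the 33 named genes called here passed. Under the 10 other settings tried for them (no table term, a pseudocount of 0.1, rescaling to a common sum, quantile normalization and each library left out), 11 passed in each: Asb2, Cd244, Dtx1, Dusp1, Gzmb, Itgax, Ocstamp, Ptafr, Slc26a11, Spi1 and Tnfrsf23. None of the 10 named genes that fell passed in all 10. Without CTdel replicate 1 the adjusted p of Gata2 was 0.230, of Zfpm1 0.199, of Cpa3 0.237, of F2r 0.160, of Mycn 0.267, of Flt3l 0.210, of Mir1949 0.160, of Hk3 0.370 and of Dmpk 0.0657, and without CTdel replicate 2 that of Muc13 was 0.228.

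By list, NF-kB targets were higher in CTdel in 17 of 17 genes, with a median of 1.56 (camera adjusted p = 3.55e-13, and adjusted p = 0.639 with an estimated correlation). Of these, 3 rose over all genes and 12 adjusted over the list alone, and the 3 were the inhibitors Nfkbie (2.27), Nfkbia (2.32) and Tnip1 (1.56). Without CTdel replicate 1 the adjusted p of these genes was 0.0551, 0.131 and 0.300, and with the table left out of the model that of Nfkbia was 0.266. Interferon-response genes were higher in 24 of 24, with a median of 2.05 (adjusted p = 3.55e-13, and adjusted p = 0.75 with an estimated correlation). Over all genes 0 of them passed, and 12 did adjusted over the list alone. The median of the list was 1.08 in replicate 1 and 2.42 in replicate 2. In the same comparison the tested histone cluster genes had a median of 0.35 (0.71 and 0.05 in replicates 1 and 2), with 1 past the threshold. The small nuclear and Y RNA genes had one of 0.54 (1.44 and −0.69), with 0 past it. Cxcl10 had 55.1 ± 57.7 (log2 change 3.95, adjusted p = 0.0631), and the RNA sensor Ifih1 23.9 ± 1.33 against 4.11 ± 3.42 in con (log2 change 2.46, adjusted p = 0.094). Of 13 myeloid markers 3 rose: Spi1, the master factor of myeloid cells (3.03, adjusted p = 0.017), the signalling adaptor Tyrobp (2.34) and the lysosomal protein Cd68 (1.41). The list had a median of 0.33 (adjusted p = 0.00214, and adjusted p = 0.75 with an estimated correlation), 5 rose and 2 fell adjusted over the list alone, and without con replicate 1 its adjusted p was 0.124. Without CTdel replicate 2 the adjusted p was 0.0604 for Tyrobp, 0.323 for Cd68, 0.135 for Itga4 and 0.0542 for Itgal. With the table left out of the model it was 0.200 for Tyrobp and 0.211 for Cd68. Of 17 homing and adhesion receptors Itgal (2.08, adjusted p = 0.02) and Itga4 (2.19, adjusted p = 0.0282), integrin subunits that bind vessel walls, rose, while the chemokine receptor Cxcr4 had a log2 change of 1.71 (adjusted p = 0.082). That list had a median of 0.33 (adjusted p = 0.0183, and adjusted p = 0.639 with an estimated correlation), with 6 genes higher and 2 lower adjusted over the list alone, and an adjusted p of 0.0884 without con replicate 2.

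T-lineage genes lay higher in CTdel (5 tested, median 0.49, adjusted p = 0.0277, and adjusted p = 0.639 with an estimated correlation), and erythroid and megakaryocyte markers lower in 7 of 7 (median −0.78, adjusted p = 0.00277, and adjusted p = 0.639 with an estimated correlation), with Klf1 at −1.90 (adjusted p = 0.0584) and Tal1 at −1.19 (adjusted p = 0.0632). Leaving out con replicate 1, con replicate 2 or CTdel replicate 1 ended the T-lineage call, with adjusted p from 0.0618 to 0.0895, as did quantile normalization (0.110) and fitting without a filter on low genes (0.134). Adjusted over the list alone 2 T-lineage genes rose and 3 erythroid and megakaryocyte markers fell, against 0 over all genes. Ribosome biogenesis and MYC targets lay lower (median −0.36, adjusted p = 0.00162, and adjusted p = 0.907 with an estimated correlation), although its member with the smallest p, Pes1, had a positive change of 0.78, and without con replicate 2 the list turned upward (adjusted p = 0.508). Of 7 mast cell and basophil markers Gata2 and Cpa3 fell, and the list did not pass (adjusted p = 0.848). Slc7a11, the cystine transporter, rose by 1.87 (adjusted p = 0.0261) within a list of 19 unfolded protein and amino acid stress genes that did not pass (adjusted p = 0.524), and had an adjusted p of 0.160 without CTdel replicate 1 and 0.241 with the table left out of the model. The p53 response (median 0.13, adjusted p = 0.425), cell cycle genes (median 0.01), glycolysis, cholesterol synthesis, cytosolic ribosomal proteins, oxidative phosphorylation, heat shock proteins, chromatin modifiers, the BCL2 family, Notch pathway components, B-lineage genes and IL-3 and STAT5 targets did not pass either, with adjusted p from 0.143 to 0.848. Several passed with a library left out: without con replicate 1 the p53 response lay higher (0.0169) and heat shock proteins (0.00058), oxidative phosphorylation (0.00725) and cell cycle genes (0.0357) lower. Without con replicate 2, by contrast, cell cycle genes (0.00612) and cholesterol synthesis (0.00749) lay higher. Without CTdel replicate 1 B-lineage genes lay higher (0.0152), and without CTdel replicate 2 the p53 response higher (0.0143) and glycolysis lower (0.0425). Without a filter on low genes the count of 156 was 0, with 1592 genes at an unadjusted p under 0.05 in limma. It was 729 and 731 without ICN replicates 1 and 2 and 730 when the con and CTdel libraries were fitted alone, and these 730 included all 156.

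**Figure D2:**
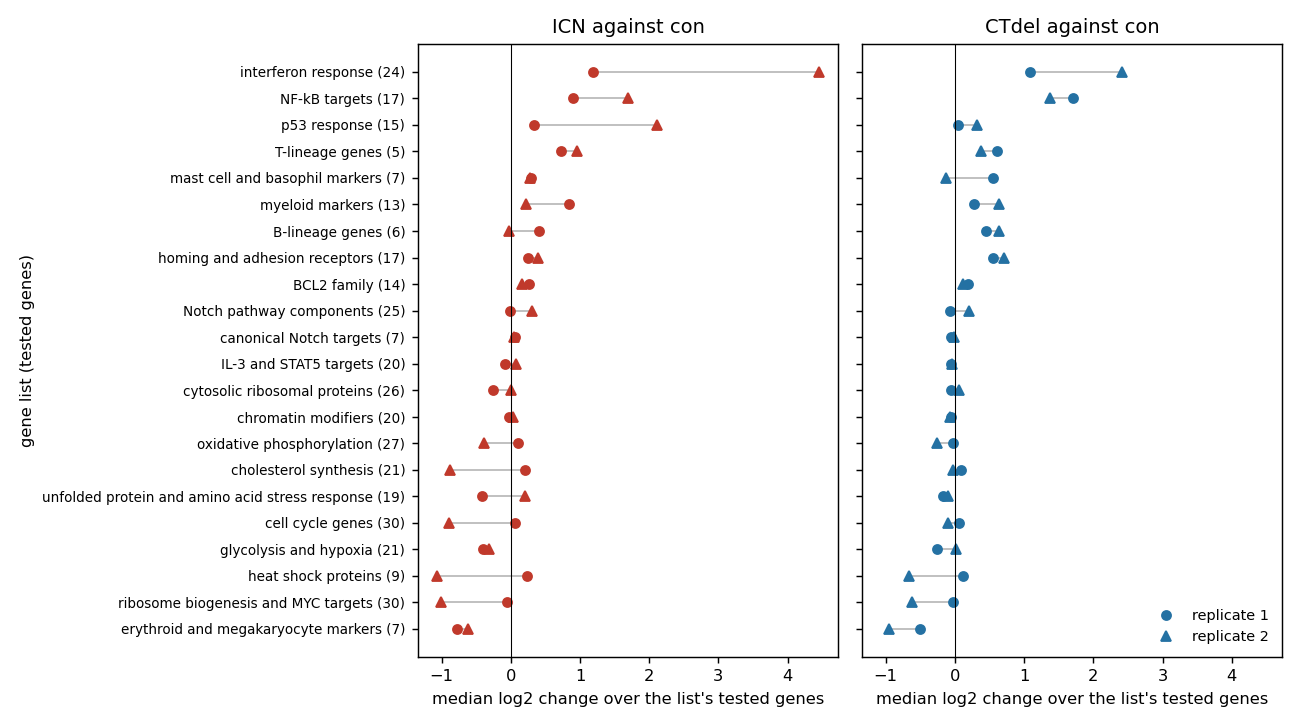
Median log2 change over each list's tested genes against con of the same table (horizontal axis, on the log2(FPKM + 1) scale) for ICN and CTdel, with circles for replicate 1 and triangles for replicate 2. The interferon response medians are 1.19 and 4.46 in ICN, and the p53 response lies higher in ICN replicate 2 than in the other transfected libraries.

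Set against ICN itself, CTdel differed in 2 genes, both lower. Park2 stood at 0.865 ± 0.912 in CTdel against 77.5 ± 28.3 in ICN (SD, n = 2; log2 change −5.44), and Pbld1 at 0.375 ± 0.247 against 22 ± 1.46 (log2 change −4.07), each with an adjusted p of 0.0237 in limma's test. In CTdel neither differed from con, with log2 changes of 0.10 and −0.02. With a pseudocount of 0.1 in place of 1, both had an adjusted p of 0.208 here and 0.0502 in ICN against con. Among the genes that did not pass, Tnfrsf23 (2.42), Cd244 (2.95), Ocstamp (3.65), Asb2 (2.73) and Itgal (1.55) had the smallest p on the higher side, with adjusted p from 0.212 to 0.296, and Dtx1 had a log2 change of 2.18 (adjusted p = 0.326). On the lower side were Casc4 (−2.25) and the brain cytoplasmic RNA Bc1 (−2.06), each with adjusted p = 0.326, and Snord11, listed at 0 in CTdel and con and at 4.1 and 4.05 in ICN (adjusted p = 0.212). The lowest values above 0 at the length of Snord11, 63 bases, were 2.05 and 2.03 in the ICN libraries, so it may rest on few reads. The genes that passed in CTdel against con but not in ICN against con are thus not shown to differ between the forms.

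The p53 response lay lower in CTdel than in ICN in 14 of 15 genes, with a median of −1.07 (camera adjusted p = 7.01e-06, and adjusted p = 0.784 with an estimated correlation). The median was −0.40 in replicate 1 and −1.74 in replicate 2, and without ICN replicate 2 the adjusted p was 0.0162. In the same comparison the tested histone cluster genes had a median of −0.70 and the small nuclear and Y RNA genes one of −0.84, with 0 past the threshold. Cdkn1a, the cell cycle inhibitor p21, had 537 ± 401 in ICN and 146 ± 57.3 in CTdel (SD, n = 2; log2 change −1.69, adjusted p = 0.665), and Mdm2, the ligase that p53 induces against itself, had −1.59. Interferon-response genes lay lower, with a median of −0.84 (adjusted p = 0.000259, and adjusted p = 0.784 with an estimated correlation), but without ICN replicate 2 they turned higher (adjusted p = 0.115). Cell cycle genes (median 0.35, adjusted p = 3.01e-06), cholesterol synthesis (median 0.32, adjusted p = 0.000108), glycolysis and hypoxia (median 0.28, adjusted p = 0.000259), cytosolic ribosomal proteins (median 0.12, adjusted p = 0.00557) and ribosome biogenesis genes (median 0.15, adjusted p = 0.0272) lay higher, with Sqle at 0.96, Aurka at 0.61 and Hk1 at 0.48. With an estimated correlation the adjusted p of these 5 ran from 0.784 to 0.813, and without ICN replicate 2 the cell cycle, cholesterol and ribosome biogenesis lists turned downward (adjusted p = 0.764, 0.673 and 0.0301). Without CTdel replicate 2 the adjusted p for glycolysis was 0.216, without CTdel replicate 1 that for ribosome biogenesis was 0.328, and for ribosomal proteins it was 0.369 without CTdel replicate 1 and 0.696 without ICN replicate 1. With quantile normalization the adjusted p was 0.124 for ribosome biogenesis and 0.839 for ribosomal proteins. The other 15 lists did not pass, with adjusted p from 0.0883 to 0.937, but 7 of them passed under another setting. NF-kB targets (adjusted p = 0.0938) had medians of opposite sign in the replicates, 0.57 and −0.60. They lay higher in CTdel without ICN replicate 2 (6.01e-09), CTdel replicate 2 (2.93e-09), con replicate 1 (0.0363) or con replicate 2 (0.0363). The list turned lower without ICN replicate 1 (0.417) or CTdel replicate 1 (0.305). The count of 2 genes was 891 without ICN replicate 1 and 9 without ICN replicate 2, 7 without CTdel replicate 1, and 788 genes had an unadjusted p under 0.05. Without a filter on low genes it was 0 in limma, with 1386 at an unadjusted p under 0.05.

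Taking both forms together, 123 genes changed against con, 112 higher and 11 lower. Besides Notch1 they included the interferon-response genes Cxcl10 (log2 change 4.78, adjusted p = 0.0336) and Ifit2 (2.03, adjusted p = 0.0436), along with Gzmb (4.55), Dusp1 (3.85), Ptafr (3.24) and Slc11a1 (2.51) on the higher side, and Dmpk (−1.81), Flt3l (−1.55), Mycn (−1.56) and Gata2 (−1.44) on the lower. By list, interferon response (adjusted p = 4.25e-16), NF-kB targets (1.74e-11), p53 response (0.00203), T-lineage genes (0.00359) and myeloid markers (0.00683) lay higher, and erythroid and megakaryocyte markers (0.00383), ribosome biogenesis (7.2e-06) and glycolysis (0.00963) lower. The medians were larger in replicate 2 than in replicate 1 for the interferon response, where that of replicate 2 was 3.41, and for the p53 response (0.28 in replicate 1 and 1.16 in replicate 2). The tested histone cluster genes had a median of 0.76 and the small nuclear and Y RNA genes one of 0.92. None of the 8 lists held with an estimated correlation, where the adjusted p ran from 0.739 to 0.847. Without con replicate 2 the adjusted p was 0.367 for the p53 response and 0.817 for ribosome biogenesis. Without con replicate 1 it was 0.337 for myeloid markers and 0.375 for glycolysis. Those lists also lost their calls without ICN replicate 1 (myeloid markers, 0.167) and CTdel replicate 1 (glycolysis, 0.0954). Of the 14 lists that did not pass, 5 passed under another setting, among them cell cycle genes, lower without ICN replicate 1 (9.05e-06) or con replicate 1 (0.000121). Across genes, which are not independent replicates, the changes of ICN and CTdel against con had a Pearson correlation of 0.705 and a covariance of 0.231, against 0.503 and 0.0639 for simulated unchanged groups that share the same con libraries, a difference in covariance of 0.167. Part of the shared direction may therefore come from the shared con libraries. Between the tables, where the compared changes share no library, the correlation was 0.426 and 0.276, against 0.00384 simulated. Dusp1 and Ptafr were called higher with both forms, where simulated unchanged groups with the same con libraries shared 0.02 genes on average and independent lists of these sizes would share 0.0521. Neither figure can say whether this overlap is large. The simulated groups had no changed genes, and the 2 comparisons share con libraries and each gene's spread. Without a filter on low genes 0 genes passed in limma, with 2098 at an unadjusted p under 0.05. The count of 123 was 48 without con replicate 2, 1240 and 577 without ICN replicates 1 and 2, and 189 and 249 without CTdel replicates 1 and 2.

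**Figure D3:**
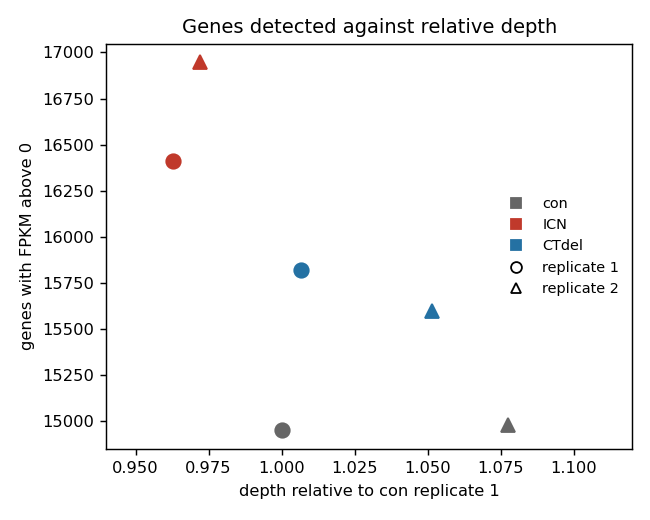
Genes with FPKM above 0 (vertical axis) against depth relative to con replicate 1 (horizontal axis) in each library, by group and replicate. Both ICN libraries lie above the others in genes and below them in depth.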

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

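All tests of explanations in this part were chosen after the results were seen.

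Park2 and Pbld1 differed between CTdel and ICN by −5.44 and −4.07 on the log2 scale, and Casc4 showed the same order, at FPKM 23.7 and 18.4 in ICN, 3.76 and 3.14 in con, and 6.56 and 1.8 in CTdel. Reads of the transfected Notch1 sequence would keep 1 ratio to Notch1 in both ICN libraries, but that ratio differed between them by a median of 6.02 times over the 3 genes, and their transcripts share 0 stretches of 25 bases with mouse Notch1. The species of the ICN sequence is not given, so the count of shared stretches cannot decide for an insert from another species. Sequence of the shared Clover plasmid would show in con too, where the genes stood at a median of 0.0173 of their ICN level. Tested neighbours within 500 kb had median log2 changes in ICN of −0.66 for Park2 (2 genes) and 0.02 for Pbld1 and Casc4, but Trim69, near Casc4, had the same order, at 3.3 and 9.12 in ICN, 0.18 and 0.25 in con, and 0.92 and 0.46 in CTdel (adjusted p = 0.144 in ICN). Other sequence of the ICN plasmid, if read in proportion to Notch1, would keep 1 ratio to Notch1 too. The median difference of 6.02 times argues against that for these 3 genes. An effect of ICN in these cells, or sequence carried by the ICN plasmid alone and read in another proportion, may lie behind them, and neither was tested.

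The ICN libraries held more genes with FPKM above 0 than the others, 16413 and 16946 against 14951 and 14981 in con. Deeper sequencing would shrink the FPKM of a single read in ICN, but from the lowest values of small RNA genes of equal length the mean depth of ICN was 0.931 of that of con. An even background of genomic DNA would add the same FPKM to genes of every level, but the median added FPKM was larger in genes at 0.5 to 2 in CTdel of the other table than in silent genes, by 0.11 in replicate 1 (bootstrap interval 0.07 to 0.14) and 0.38 in replicate 2 (0.35 to 0.46). That comparison cannot decide on silent genes, which weigh most in the count of genes above 0. Their median FPKM was 0 in con and 0.01 and 0.02 in ICN replicates 1 and 2, so genomic DNA as a part of the pattern stays open. A wider set of genes at low level in ICN cells, and RNA quality or library differences that scale with a gene's level, also stay open and were not tested.

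ICN replicate 2 stood apart, with correlations of 0.896 to 0.949 over genes to the other libraries, and the interferon and p53 medians were largest in it. Con replicate 2 was nearly as distant, at 0.896 to 0.956. The con replicates also differed about as much as the ICN ones (SD of the difference over genes 0.563 and 0.574, against 0.423 in CTdel). ICN replicate 1 correlated more closely with CTdel replicate 1 (0.982), CTdel replicate 2 (0.965) and con replicate 1 (0.954) than with ICN replicate 2 (0.949), and held genes that were at FPKM 0.2 or less in con and in ICN replicate 2 but at 5 or more in CTdel replicate 1. Carryover of CTdel replicate 1 RNA would give these genes 1 common ratio between the libraries, but over 10 such genes the 90th percentile of the ratio was 12.5 times the 10th. It ran from 0.0075 for Apol7c and 0.0303 for Ltc4s to 0.342 for Il1a and 0.42 for Csf1r, so carryover cannot be the whole source, though a small share could be. A response that ICN and CTdel share in cells handled together stays open.

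Bc1 had opposite changes in the forms, higher than con in both ICN libraries and lower in both CTdel libraries, −2.06 between them on the log2 scale, and this opposition was not itself tested. Some genes listed in a single table, and so outside the tests, stood above con in a library with an ICN form: in the table of replicate 1 the microRNA genes Mir686 (FPKM up to 79.6), Mir5136 (19.8), Mir5114 (7.28) and Mir6999 (6.35), and in the table of replicate 2 the MHC class II gene H2-Ab1 (5.45).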

How the results depend on the processing

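The fits with weights per group and without small RNA and histone genes were chosen after the data were seen. Of 546 changes of 182 named genes over 10 settings, which leave out the fit without a filter on low genes, 5021 of 5460 values kept their side of the threshold (237 of these, never called, had the opposite sign), 77 lost a call, 362 gained one and 0 called changes turned. Only 39 of the 546 changes were called, so the share that kept its side mostly describes changes that were never called. All 77 lost calls came from these 39. Without filtering low genes, 0 genes passed in limma in ICN, CTdel, CTdel against ICN and both forms, where 2328, 1592, 1386 and 2098 had an unadjusted p under 0.05, so all 39 calls of named genes were lost there; the cause was not tested. CTdel against ICN had 0 genes with a pseudocount of 0.1 (744 at an unadjusted p under 0.05) and 1 gene at FPKM of at least 5. At a threshold of 0.1 the counts were 11 for ICN, 262 for CTdel and 293 for both forms. With only the compared groups fitted, which leaves out the other groups' spread, they were 162 for ICN and 730 for CTdel, and with library weights per group (0.463 for con, 0.398 for ICN and 5.43 for CTdel) 416 for CTdel. Without small RNA and histone genes they were 8 for ICN and 194 for both forms. List calls fell to 0 in all 4 comparisons with an estimated correlation, a test that rests on the 2 residual degrees of freedom. Over the libraries left out in turn, genes ranged from 11 to 1470 in ICN, 109 to 731 in CTdel, 2 to 891 in CTdel against ICN and 48 to 1240 for both forms, lists from 7 to 10, 6 to 9, 6 to 8 and 6 to 11, and the correlation of changes from 0.531 to 0.814. With no replicate block the counts were 3, 130, 2 and 132, with 113 of the 156 CTdel genes shared. Same-numbered libraries deviated together by −0.0988 (con and ICN), 0.326 and 0.236 (CTdel with con and with ICN). By this check the numbers pair CTdel weakly with con and with ICN, but do not pair con with ICN, although all share a table. Other scalings kept every count within 1.5 times, though single list calls were lost. Of lists that did not pass, 3 of 11 in ICN, 8 of 15 in CTdel, 7 of 15 in CTdel against ICN and 5 of 14 for both forms passed under another setting. Without read counts, low genes and genes listed at 0 cannot be told from undetected ones.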

Other observations

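The enrichment of annotation terms and the values per RNA class were chosen after the results were seen. Among the genes higher in CTdel than con, 2 of 633 Biological Process terms passed. Cell-cell adhesion held 6 of 35 tested genes where 0.492 were expected (adjusted p = 0.00372), among them Ptprc, the leukocyte phosphatase CD45, Esam and the integrins Itga4 and Itgal. The response to bacterial molecules held 8 of 78 where 1.1 were expected (adjusted p = 0.00372), among them the kinase Jak2, the ubiquitin ligase Peli1 and Slc11a1. Inflammatory response, with Tlr2, a sensor of bacterial lipoproteins, Mefv and Tgm2, did not pass in CTdel (adjusted p = 0.0691) and did for both forms together (7 of 67 genes, adjusted p = 0.00264). Notch1 itself is among those 7, and its plasmid reads are not separated, but with Notch1 left out of the called genes the term still passed (6 of 67, adjusted p = 0.0181). Among the genes lower in CTdel, megakaryocyte differentiation had an adjusted p of 0.0471, but it rests on Gata2 and Zfpm1 among 7 called genes with a term, and without CTdel replicate 1 neither gene passed (adjusted p = 0.230 and 0.199). Simulated random lists gave a passing term in 0 of 20 runs. Genes drawn at random are what the hypergeometric test assumes, and these lists were longer than the 7 genes lower in CTdel. The runs thus check the calculation and lend no support to the terms above.

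Dtx1 did not follow the level of Notch1 across the libraries with an ICN plasmid. Ordered from the highest to the lowest Notch1 FPKM (888, 190, 84.9 and 25.4), Dtx1 stood at 1.02, 2.86, 15.5 and 8.71. Both ICN libraries come before both CTdel libraries in this order, so the level of Notch1 and the form cannot be told apart. Within CTdel the library with more Notch1 had more Dtx1, and within ICN it had less. The interferon medians in the same order were 4.46, 1.19, 1.08 and 2.42, and those of the p53 response 2.12, 0.34, 0.05 and 0.32. Levels of transcripts that usually lack a poly(A) tail varied too, and were not tested as classes: FPKM of 68 replication-dependent histone cluster genes summed to 203 and 900 in con, 390 and 1306 in ICN and 410 and 1032 in CTdel, replicate 1 before replicate 2. Those of 19 small nuclear and Y RNA genes summed to 65.3 and 98.4, 280 and 155, and 163 and 68.0. Of 128 olfactory receptor genes, 32 and 30 were above 0 in con, 54 and 75 in ICN and 41 and 33 in CTdel.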
